A study of Oncorhynchus mykiss with 9 samples.

How the data were processed

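Total RNA of rainbow trout liver was sequenced in 9 libraries, 3 each of control, moderate hypoxia and acute hypoxia, and the groups were taken from the sample labels. The deposited values are FPKM per gene and library, per the file headers, beside which the authors give log2 fold changes, p-values and FDR for each pair of groups. Per the submitters' processing notes the upstream tools included Bowtie2 2.2.8 and TopHat2 2.1.1; the genome build, the counting tool and the test behind the authors' p-values were not given in the sources used here. The file stacks 3 tables, for moderate hypoxia with control, acute hypoxia with control and acute with moderate hypoxia, of 42127, 42038 and 42128 genes. Moderate hypoxia values in the tables of moderate hypoxia with control and with acute hypoxia are identical (largest difference 0), while the table of control with acute hypoxia comes from a quantification with other gene models. Control and moderate hypoxia were therefore taken from their joint table and acute hypoxia from its table with moderate hypoxia, and the remaining table served as an alternative. Read counts were not used here, so depth is given only as a ratio to the first control library, read from the ratios of low values. An annotation table of the species supplied gene names only. Nothing in the labels says that the 3 libraries of a group came from separate fish, so the p-values may measure technical spread.

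Genes with a mean of at least 1 FPKM over the 9 libraries were kept (13803), and log2(FPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean trend), all 3 groups in 1 fit and no covariate. The added 0.5 shrinks log2 fold changes of genes with low FPKM. For such genes they understate the ratio of FPKM means, and rankings by fold place these genes lower. Benjamini-Hochberg adjusted p under 0.05 over all genes counted as past the test, without a fold threshold. Where the median log2 difference of all genes exceeded 0.1 in size, changes are reported relative to it and counts are given under the deposited scaling and under median-of-ratios scaling. The adjusted p beside such a relative change is limma's for the change before the median was subtracted, tested against 0. Tests of 38 lists of pathways and cell-type markers used limma's camera with a preset correlation between genes of 0.01, on lists with at least 5 tested genes, adjusted over the lists. Camera asks whether members moved relative to other genes, so its direction can differ from the sign of a list's median. Camera with a correlation estimated from the data, and fry, were run beside it. Fry asks whether members moved together in 1 direction, without setting them against other genes. A list whose members moved both ways can therefore miss its call. Members were matched by gene symbol or product name, and are counted as higher or lower after adjustment over all genes and after adjustment over the list alone. The overlap of the 2 hypoxia groups was set against independent lists and against 50 simulations without changed genes, in which both groups share 3 simulated controls. For the glut1 genes, below the filter, limma was run without it, with exact permutation tests of log2(FPKM + 0.5).

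The main analyses, the lists and the following rule for named genes were fixed before the data were examined. For each hypoxia group against control the 10 highest and 10 lowest genes were selected among those past the test with an absolute log2 fold change of at least 1, groups that do not overlap and a name other than uncharacterized, and 6 and 6 for acute against moderate hypoxia. Selected too were up to 4 members of each list with the smallest p in each comparison with control, the members of the HIF pathway and HIF target lists past the test, and the glut1 genes. The text gives values for part of the genes so selected, and the others are not reported here. A self-test on simulated data recovered 94.0%, 97.0% and 97.0% of genes changed by 1 on the log2 scale in moderate against control, acute against control and acute against moderate hypoxia, and 14.9%, 31.3% and 32.8% of those changed by 0.5, with 10 false calls of 149, 10 of 161 and 12 of 165. It changed 67 genes at each of these sizes, with independent noise and no shift of all genes. Far more genes were called in the real comparisons, so these rates need not hold there. Alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 5 FPKM, median-of-ratios and quantile scaling, cyclic loess, limma without the mean trend, with robust variances or with the 2 compared groups alone, a replicate block, an added fold threshold, other set tests, stricter matching of members, the other quantification, and each library left out in turn. Of these, cyclic loess, quantile scaling of the lists, stricter matching and the other quantification were chosen after seeing the data, as were 2 scalings of the glut1 genes and the tests of explanations in the closing section. Among tested genes 51, in 13 sets of which the largest is a set of 15, share all 9 values with another gene, so they are not separate measurements, and values of near-identical copies such as heme oxygenase and polyubiquitin genes are uncertain. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.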

Results

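Gene expression was measured by RNA sequencing of total RNA from the liver of rainbow trout (Oncorhynchus mykiss), a salmonid fish of cold, well-oxygenated water. The 9 libraries fall into 3 groups of 3, labelled control, moderate hypoxia (oxygen shortage) and acute hypoxia, and the design text names an exposure of 12 h in words that may bind it to both treatments or to one. The oxygen levels were not given in the sources used here, and reoxygenated fish were not analysed here. Expression was deposited as FPKM (fragment numbers scaled to transcript length and library total), so read totals are unknown and no counting interval can be given. Judged from the steps between low values, sequencing depth relative to the first control library ran from 0.946 to 1.29. A value above 0 was listed for 29598 to 30611 genes per library. Genes at 1 FPKM or more numbered 13078 to 13491 in control, 14196 to 15166 in moderate hypoxia and 12724 to 13098 in acute hypoxia. The 10 most abundant genes held 26.1% to 29.7% of the FPKM total of a library.

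Principal component analysis (PCA) of the 13803 tested genes separated the 3 groups. The first component, with 44.1% of the variance, placed the moderate hypoxia libraries at scores of 26.8 to 39.1, the controls at -15.4 to -10.8 and the acute hypoxia libraries at -23.2 to -15.8. The second component, with 21.1%, set the controls (17 to 24.1) apart from acute hypoxia (-21.6 to -15.4). Across genes, which are not independent replicates, Pearson's correlation of log2 values was 0.983 to 0.989 within groups, 0.971 to 0.978 between control and acute hypoxia and 0.962 to 0.970 between control and moderate hypoxia. No pair of libraries held identical values.

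**Figure D1:**
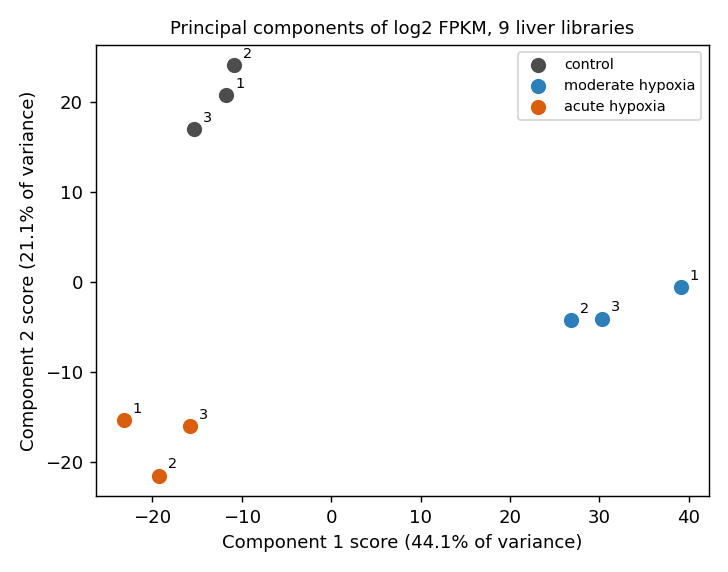
Scores of the 9 liver libraries on the first and second principal component of log2(FPKM + 0.5), one point per library, with its replicate number beside it and the percent of variance on each axis. The moderate hypoxia libraries lie at 26.8 to 39.1 on the first component, and control and acute hypoxia lie at opposite ends of the second.

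Acute hypoxia was set against control to ask which liver genes differ under acute oxygen shortage. Target genes of the hypoxia-inducible factor (HIF), the transcription factor that answers low oxygen, and genes of glycolysis, which yields ATP without oxygen, rose, while genes of cholesterol synthesis and of ribosome biogenesis fell. Of 40 HIF targets 12 were higher and 3 lower, of 30 glycolysis genes 10 were higher and 1 lower, and 25 of 34 cholesterol synthesis genes and 21 of 71 ribosome biogenesis genes were lower with none higher. The set test camera gave adjusted p = 2.28e-08, 9.61e-08, 7.06e-19 and 1.89e-11 in that order, and adjusted p = 0.015, 0.0785, 0.22 and 0.233 with an estimated correlation.

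The HIF targets included epo (ncbi_110531655), the hormone of red cell formation, which rose from 0.379 ± 0.0220 to 3.12 ± 0.492 FPKM (SD, n = 3). Its fitted log2 fold change, with 0.5 added to FPKM, was 2.03 ± 0.13 (SE, limma adjusted p = 9.72e-06). The FPKM means themselves differed 8.25-fold, which is more than that fitted value gives. Of the heme oxygenase genes, whose enzyme breaks down heme, hmox (ncbi_110485518) rose from 7.49 ± 0.579 to 55.3 ± 11.6 FPKM (log2 fold change 2.78 ± 0.16, adjusted p = 6.87e-06) and its copy hmox (ncbi_118936555) by 2.54 on the log2 scale. The angiogenic growth factor vegfaa (ncbi_110529696) rose by 0.86 and ankrd37 (ncbi_110534293) by 1.57, whereas ndrg1a (ncbi_110488041), also on the list, fell by 0.79. Adjusted over the list alone, 17 HIF targets were higher and 3 lower. In the oxygen-sensing pathway itself 5 of 20 genes were higher and none lower (camera adjusted p = 0.00496; 5 and 2 adjusted over the list alone; adjusted p = 0.233 with an estimated correlation). These were prolyl hydroxylases, which mark HIF for degradation: Egln3 (ncbi_110505778) rose by 2.03 ± 0.14 (SE), Egln3 (ncbi_110497687) by 1.76, egln1 (ncbi_101268917) by 1.53 and EGLN2 (ncbi_110507058) by 1.43. The fifth, Egln1 (ncbi_110486061), at 0.63 (adjusted p = 0.029), was not called when any of the 6 libraries was left out, the highest adjusted p being 0.0971. The largest rise of all genes named in this comparison was that of fih1 (ncbi_101268916), annotated as the factor inhibiting HIF-1 alpha, an asparaginyl hydroxylase, from 2.08 ± 0.0567 to 32.6 ± 2.73 FPKM (log2 fold change 3.68 ± 0.12, adjusted p = 9.27e-08).

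Among glycolysis genes, 15 were higher and 3 lower adjusted over the list alone. The triosephosphate isomerase gene tpi1b (ncbi_110489325) rose from 23.9 ± 0.546 to 63.5 ± 3.70 FPKM (log2 fold change 1.39 ± 0.09, adjusted p = 9.56e-06), pgam1b (ncbi_110493407), a phosphoglycerate mutase, by 1.73 and pgk1 (ncbi_110537531), phosphoglycerate kinase, by 0.63. The lactate transport list was called higher on 1 member past the test of 6 (camera adjusted p = 0.0201; 1 adjusted over the list alone; adjusted p = 0.222 with an estimated correlation), and the call was lost without acute hypoxia replicate 1 (adjusted p = 0.0656). That member was the monocarboxylate transporter SLC16A7 (ncbi_110532449), which rose by 1.09. Gluconeogenesis was not called as a list (1 of 13 higher, 2 lower), but G6PC (ncbi_110499065), glucose-6-phosphatase, which releases glucose from the liver, fell from 71.3 ± 7.79 to 38.7 ± 3.91 FPKM. The glycogen-targeting phosphatase subunit ppp1r3cb (ncbi_110491403) rose by 1.56 ± 0.10 (SE, adjusted p = 9.72e-06). Genes of amino acid breakdown rose as a list, with 14 of 53 higher and none lower (camera adjusted p = 1.92e-06; 18 higher and 2 lower adjusted over the list alone; adjusted p = 0.0785 with an estimated correlation). Tat (ncbi_110494358), tyrosine aminotransferase, rose by 1.97, Mat1a (ncbi_110530927), which makes S-adenosylmethionine, by 1.14 and cbs (ncbi_100136726), cystathionine beta-synthase, by 0.90.

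Adjusted over the list alone, 32 of the 34 cholesterol synthesis genes were lower. The mevalonate pathway enzymes hmgcs1 (ncbi_110523168), idi1 (ncbi_100301790) and FDPS (ncbi_110520852) fell from 20.3 ± 1.66 to 4.07 ± 1.59, from 21 ± 0.894 to 4.42 ± 2.01 and from 22.1 ± 0.731 to 6.0 ± 2.45 FPKM, with adjusted p = 0.000292, 0.000407 and 0.0011. Fatty acid oxidation genes were lower as a list, with 1 of 40 higher and 6 lower (camera adjusted p = 0.00556; 1 and 13 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation). The carnitine palmitoyltransferase gene CPT1A (ncbi_100329197), whose enzyme admits fatty acids to mitochondria, fell by 1.46 on the log2 scale, while PPARA (ncbi_110521393), the transcription factor that drives the pathway, rose by 0.92. Lipogenesis genes were lower, with 3 of 30 higher and 6 lower (camera adjusted p = 0.00835; 3 and 15 adjusted over the list alone; adjusted p = 0.233 with an estimated correlation). The lipid droplet gene PLIN2 (ncbi_110531797) fell from 21.2 ± 8.33 to 3.42 ± 0.493 FPKM, and the desaturase gene SCD1 (ncbi_110502614) fell by 0.93, while the desaturase gene scdb (ncbi_110530485) rose by 1.12 and dgat2 (ncbi_110537459), which completes triglycerides, by 0.82. Bile acid and xenobiotic genes were called higher although 2 of 40 were higher and 3 lower (camera adjusted p = 0.00725; 5 and 4 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation); CYP8B1 (ncbi_110530492), a bile acid hydroxylase, rose by 0.61.

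Ribosome biogenesis genes lower in acute hypoxia numbered 36 adjusted over the list alone. They included the nucleolar genes nop2 (ncbi_110537356), which fell by 0.67, nhp2 (ncbi_110533406), which fell by 0.65, and wdr43 (ncbi_110506265), which fell by 0.59. Proteasome genes were also lower, 9 of 93 with none higher on both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 5.14e-08; adjusted p = 0.233 with an estimated correlation). Of 8 tested cell cycle genes 4 were lower on both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.000427; adjusted p = 0.0791 with an estimated correlation). They were the replication helicase genes mcm3 (ncbi_110529168), which fell by 1.46, mcm4 (ncbi_110530465), which fell by 0.92, and mcm7 (ncbi_110489022), which fell by 0.75, and the thymidylate synthase gene tyms (ncbi_110489946), which fell by 0.70. Glucocorticoid-responsive genes rose, with 7 of 17 higher and none lower on both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 2.15e-06; adjusted p = 0.0785 with an estimated correlation). Among them fkbp5 (ncbi_110528325), a chaperone of the glucocorticoid receptor, rose from 0.697 ± 0.00306 to 5.32 ± 2.36 FPKM, zbtb16a (ncbi_110537608) by 1.67 on the log2 scale and the kinase gene sgk1 (ncbi_110529254) by 1.5. Insulin and growth factor signalling genes were higher, 6 of 31 against 1 lower (camera adjusted p = 0.000427; 9 and 3 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), among them the transcription factor genes foxo1a (ncbi_110534227) at 1.10 ± 0.12 (SE) and Foxo3 (ncbi_110529912) at 0.95.

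Inflammation genes were lower as a list, with 2 of 32 higher and 8 lower (camera adjusted p = 0.0144; 3 and 14 adjusted over the list alone; adjusted p = 0.688 with an estimated correlation). The call was lost without control replicate 2 (adjusted p = 0.052) and without acute hypoxia replicate 1 (adjusted p = 0.187). Relb (ncbi_110507414), a subunit of the inflammatory transcription factor NF-kappa-B, fell from 9.84 ± 4.4 to 0.993 ± 0.387 FPKM (log2 fold change -2.73 ± 0.32, adjusted p = 0.000582), and NFKBIA (ncbi_110522049), its inhibitor, fell by 1.84, while cebpd (ncbi_100379114) rose by 1.56. Endoplasmic reticulum stress genes were lower, with 3 of 57 higher and 11 lower (camera adjusted p = 0.0226; 3 and 17 adjusted over the list alone; adjusted p = 0.743 with an estimated correlation), a call lost without acute hypoxia replicate 1 (adjusted p = 0.166). The amino acid stress genes chac1 (ncbi_110522620), asns (ncbi_110488144) and atf4 (ncbi_110486127) fell by 1.63, fell by 1.18 and fell by 0.69.

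Of the cell-type markers, those of macrophages (3 of 12 lower, 4 adjusted over the list alone) and of red cells (none of 35 past the test, nor adjusted over the list alone) were called lower. Camera gave adjusted p = 0.038 and 0.0413, and adjusted p = 0.608 and 0.827 with an estimated correlation. Markers of stellate cells and fibroblasts (39 tested) and of exocrine pancreas (19 tested) were called higher with no member past the test, nor adjusted over the list alone. Their camera adjusted p was 0.038 for each, and adjusted p = 0.65 and 0.743 with an estimated correlation. Ribosomal protein genes were called lower with 2 of 191 past the test, 2 adjusted over the list alone (camera adjusted p = 0.038; adjusted p = 0.827 with an estimated correlation). One of the 2, RPS6KB1 (ncbi_110534357), is a kinase and not a ribosomal protein. All 5 of these calls were lost when single libraries were left out. That of macrophages was lost without control replicate 2 (adjusted p = 0.0711) or acute hypoxia replicate 3 (0.225). That of red cells was lost without control replicate 2 (0.165), control replicate 3 (0.0552), acute hypoxia replicate 2 (0.437) or 3 (0.552), and that of stellate cells without control replicate 1 (0.187) or acute hypoxia replicate 3 (0.389). Exocrine pancreas was lost without control replicate 1 (adjusted p = 0.627), acute hypoxia replicate 1 (0.133) or 2 (0.117). The call of ribosomal proteins was lost without control replicate 1 (0.0605), acute hypoxia replicate 2 (0.238) or 3 (0.0751), while without control replicate 2 their direction turned (0.866). Under median-of-ratios scaling the calls of exocrine pancreas (adjusted p = 0.102) and ribosomal proteins (0.178) were lost too. Markers of hepatocytes, endothelium, bile duct, granulocytes, lymphocytes and muscle were not called.

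The largest falls were those of an apolipoprotein A-IV gene (ncbi_110523359), a lipoprotein component, from 49.1 ± 12.1 to 1.05 ± 0.541 FPKM (log2 fold change -5.03 ± 0.28, adjusted p = 6.87e-06) and of the secreted phospholipase pla2g3 (ncbi_110536804), from 15.1 ± 3.37 to 0.271 ± 0.152 FPKM (-4.34 ± 0.22, adjusted p = 4.75e-06). The antimicrobial peptide gene leap-2b (ncbi_100136189) fell by 2.76 while its relative leap2 (ncbi_100136188) rose by 1.06. The immediate-early gene egr1 (ncbi_110533389) fell from 13.5 ± 0.461 to 2.05 ± 0.613 FPKM. The signalling kinase gene RIPK2 (ncbi_110526239) fell by 2.23, a C-C motif chemokine 19 gene (ncbi_110523665) fell by 2.35 and zgc:73324 (ncbi_110486266), annotated as a coenzyme Q-binding protein, fell by 2.30. Other large rises were those of PNP (ncbi_110500424), purine nucleoside phosphorylase, at 2.36 ± 0.18 (SE), of KCNC4 (ncbi_110528089), a potassium channel gene whose product name gives member 2 of the same subfamily, at 2.28, and of tfcp2l1 (ncbi_110501799) at 2.07. All 20 of the genes named for the largest changes in this comparison kept their calls with each of the 6 libraries left out and under 3 other scalings.

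In total 1075 of 13803 genes passed limma's test in acute hypoxia, 425 higher and 650 lower (39.5% higher); median-of-ratios scaling gave 585 higher and 552 lower of 1137 (51.5% higher), and 425 and 548 genes were called under both scalings. Groups did not overlap for 28.3% of genes, against 10% by chance. The count fell to 462 without control replicate 1, 588 without acute hypoxia replicate 2 and 662 without control replicate 2. With list members required to match by symbol and product name, chosen after seeing the data, the calls of the oxygen-sensing pathway (adjusted p = 0.605), fatty acid oxidation (0.105), lipogenesis (0.0987), stellate cells (0.346) and ribosomal proteins (0.0607) were lost.

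**Figure D2:**
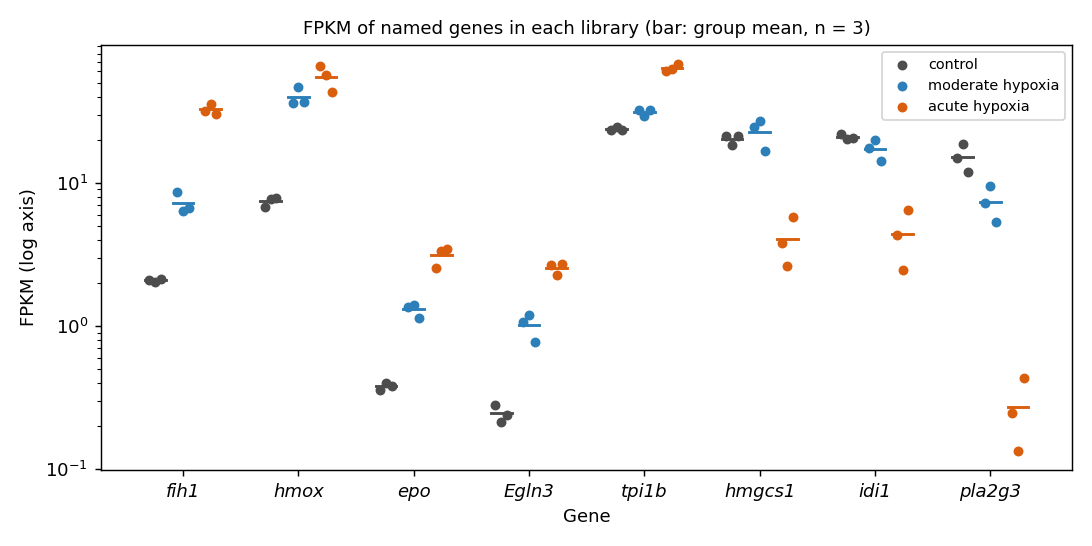
FPKM on a log axis of fih1 (ncbi_101268916), hmox (ncbi_110485518), epo (ncbi_110531655), Egln3 (ncbi_110505778), tpi1b (ncbi_110489325), hmgcs1 (ncbi_110523168), idi1 (ncbi_100301790) and pla2g3 (ncbi_110536804) in each of the 9 libraries, with points for libraries and bars for group means (n = 3). In acute hypoxia fih1 averaged 32.6 FPKM against 2.08 in control, and hmgcs1 4.07 against 20.3.

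Moderate hypoxia was set against control for the same question under the other oxygen treatment. Tested genes as a whole sat higher in the moderate hypoxia libraries, by a median of 0.15 on the log2 scale, so log2 changes in this comparison are given relative to the median of all tested genes. Genes of mitochondrial respiration, of ribosome biogenesis and of the acute phase response were lower relative to other genes, and glucocorticoid-responsive genes were higher. Of 156 respiration genes 7 were higher and 26 lower, of 71 ribosome biogenesis genes 1 and 12, of 70 acute phase genes 5 and 15, and of 17 glucocorticoid-responsive genes 11 and none. Camera gave adjusted p = 1.10e-07, 1.10e-07, 3.04e-08 and 0.00212 in that order, and adjusted p = 0.612, 0.513, 0.296 and 0.438 with an estimated correlation.

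Several HIF targets rose in moderate hypoxia although the list was not called (15 of 40 higher and 4 lower; 17 and 4 adjusted over the list alone; 8 and 6 under median-of-ratios scaling; camera adjusted p = 0.202). The heme oxygenase gene hmox (ncbi_110485518) rose from 7.49 ± 0.579 to 39.9 ± 5.96 FPKM (relative log2 change 2.17 ± 0.16, SE, adjusted p = 2.54e-05) and epo (ncbi_110531655) from 0.379 ± 0.0220 to 1.31 ± 0.140 FPKM (0.88 ± 0.13, adjusted p = 0.000424). Egln3 (ncbi_110505778) rose by 0.85, the collagen hydroxylase P4HA1 (ncbi_110499022) by 0.68, the transferrin receptor TFRC (ncbi_100653457), which takes up iron, by 0.92 and igfbp1 (ncbi_100136312), a binding protein of insulin-like growth factors, by 1.09. The oxygen-sensing pathway was not called either (6 of 20 higher, 6 adjusted over the list alone, camera adjusted p = 0.104). Among its members arnt2 (ncbi_110506172), a partner subunit of HIF, rose by 0.76, and 2 of the 6 were Arntl genes, clock transcription factors that the list took up by product name. Glycolysis genes were not called (5 of 30 higher and 1 lower, camera adjusted p = 0.704; none higher and 2 lower under median-of-ratios scaling).

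Under median-of-ratios scaling 56 of the 156 respiration genes were lower and none higher, and after cyclic loess 35 and 5, against 6 higher and 20 lower adjusted over the list alone under the deposited scaling. The complex I subunit genes ndufab1b (ncbi_110516733), ndufb7 (ncbi_100305154) and NDUFS6 (ncbi_110496462) changed by -1.46, -0.99 and -0.98, NDUFS6 from 7.36 ± 0.493 to 3.94 ± 0.346 FPKM. Ribosome biogenesis genes lower numbered 11 adjusted over the list alone and 25 under median-of-ratios scaling, with none higher in either count. Both DKC1 genes, which encode a pseudouridine synthase of ribosomal RNA, fell, DKC1 (ncbi_110509933) from 58.1 ± 3.81 to 21.1 ± 3.47 FPKM (-1.60 ± 0.15, adjusted p = 0.000145). Proteasome genes were lower, 5 of 93 against 2 higher (camera adjusted p = 2.29e-05; 1 lower adjusted over the list alone; 25 lower and none higher under median-of-ratios scaling, 16 lower and none higher after cyclic loess; adjusted p = 0.513 with an estimated correlation), among them psmb13a (ncbi_110488346) at -0.89. Cell cycle genes were lower, 4 of 8 on both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 6.21e-05; adjusted p = 0.212 with an estimated correlation), and mcm3 (ncbi_110529168) changed by -1.44 and mcm4 (ncbi_110530465) by -0.86. Of 191 ribosomal protein genes 16 were higher and 30 lower, also adjusted over the list alone, 6 and 71 under median-of-ratios scaling, and 31 and 31 after cyclic loess (camera adjusted p = 0.0001; adjusted p = 0.686 with an estimated correlation), a call lost without control replicate 2 (adjusted p = 0.0729). Among them rps29 (ncbi_110529849) changed by -1.56 and rpl24 (ncbi_110520573) by -1.21.

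Acute phase genes, whose products are plasma proteins of inflammation, numbered 5 higher and 15 lower adjusted over the list alone too, 2 and 31 under median-of-ratios scaling, and 6 and 8 after cyclic loess, where the call ended (adjusted p = 0.198, and 0.324 under quantile normalization). The complement gene c3 (ncbi_110517348) fell from 1121 ± 245 to 535 ± 57.5 FPKM (-1.20 ± 0.17, adjusted p = 0.0016) and CFB (ncbi_100653464), complement factor B, changed by -0.68, while leap2 (ncbi_100136188) rose by 0.64. Hepatocyte markers, which include plasma proteins, were called lower with them (4 of 34 higher and 9 lower, also adjusted over the list alone, 3 and 17 under median-of-ratios scaling, and 5 and 5 after cyclic loess; camera adjusted p = 0.0001; adjusted p = 0.5 with an estimated correlation). Endothelial markers (6 of 14 higher, also adjusted over the list alone, and 3 under median-of-ratios scaling; camera adjusted p = 0.104) and muscle markers (4 of 7 higher, also adjusted over the list alone, and 2 under median-of-ratios scaling; camera adjusted p = 0.23) had no lower member past the test and were not called. Cholesterol synthesis genes were called lower on 1 higher and 3 lower of 34 (1 and 2 adjusted over the list alone, 1 and 7 under median-of-ratios scaling, 1 and 4 after cyclic loess; camera adjusted p = 0.000883; adjusted p = 0.637 with an estimated correlation); hmgcs1 (ncbi_110523168) averaged 22.8 ± 5.53 FPKM against 20.3 ± 1.66 in control. Fatty acid oxidation genes were called lower with 6 of 40 higher and 5 lower, also adjusted over the list alone (5 and 18 under median-of-ratios scaling, 4 and 11 after cyclic loess; camera adjusted p = 0.00346; adjusted p = 0.513 with an estimated correlation). The higher members included PPARA (ncbi_110521393) at 1.10 and SLC25A20 (ncbi_110532875), which carries acylcarnitines into mitochondria, at 0.99. Antioxidant genes were called lower on 4 of 47 higher and 5 lower, also adjusted over the list alone (3 and 13 under median-of-ratios scaling, 4 and 10 after cyclic loess; camera adjusted p = 0.0315; adjusted p = 0.612 with an estimated correlation; adjusted p = 0.0898 without control replicate 2), although their fitted median was 0.05 (-0.11 relative to all genes) and their fitted mean 0.01; Nqo1 (ncbi_110519426), a quinone reductase, changed by -1.24 and keap1b (ncbi_118938209), which restrains antioxidant genes, rose by 0.61.

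Glucocorticoid-responsive genes higher numbered 11 adjusted over the list alone and 7 under median-of-ratios scaling. The transcription factor gene zbtb16a (ncbi_110537608) rose from 0.838 ± 0.0947 to 5.45 ± 0.303 FPKM (2.0 ± 0.12, adjusted p = 1.01e-05), FKBP5 (ncbi_110494097) rose by 1.12 and klf9 (ncbi_110525414) by 1.08. Insulin and growth factor signalling genes were higher, 13 of 31 with none lower (camera adjusted p = 0.0404; 14 adjusted over the list alone; adjusted p = 0.513 with an estimated correlation). That call was lost under median-of-ratios scaling (10 higher and 3 lower, adjusted p = 0.0977), without control replicate 2 (adjusted p = 0.0994) and without moderate hypoxia replicate 3 (adjusted p = 0.0666). Its members foxo1a (ncbi_110490984) and INSR (ncbi_100272218), an insulin receptor gene, rose by 1.37 ± 0.14 (SE) and 0.62.

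The largest rises included MSTRG.10100, an assembled transcript likened to a cell wall protein, from 4.30 ± 0.814 to 55.3 ± 16.8 FPKM (3.35 ± 0.27, adjusted p = 4.91e-05). GABRB2 (ncbi_110533363), annotated as a GABA receptor subunit, rose by 2.83, UNC13C (ncbi_110526645), known from synaptic vesicle release, by 2.78, inppl1a (ncbi_110507218), an inositol phosphatase, by 2.61 and USP9X (ncbi_110504735), a deubiquitinase, by 2.61. The largest falls included the mitochondrially encoded ATP synthase gene ATP8 (ncbi_807971), from 37.8 ± 4.04 to 5.41 ± 1.76 FPKM (-2.89 ± 0.40, adjusted p = 0.000958). The metalloproteinase gene ADAM12 (ncbi_110517068) changed by -2.85, CYP24A1 (ncbi_100136661), which inactivates vitamin D, by -2.32 ± 0.10 (adjusted p = 5.00e-06) and the apolipoprotein A-IV gene (ncbi_110523359) by -2.16. Of the 10 genes named for the largest rises 9 kept their calls with each library left out and under 3 other scalings, as did 5 of the 10 named for the largest falls. The other 5 falls were those of 2 polyubiquitin genes, a ubiquitin-like gene, a keratin gene and a urokinase receptor gene, all with near-zero values in moderate hypoxia and a wide spread in control.

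In total 4041 genes passed limma's test in moderate hypoxia, 3348 higher and 693 lower (82.9% higher); median-of-ratios scaling gave 1838 higher and 1725 lower of 3563 (51.6% higher), and 1838 and 693 genes were called under both. Under the deposited scaling groups did not overlap for 45% of genes, against 10% by chance. The shift of all genes may add to that share, which was not computed under other scalings. The count fell to 2623 without control replicate 1. Cyclic loess, chosen after seeing the data, ended the calls of acute phase (adjusted p = 0.198), hepatocyte marker (0.448), ribosomal protein (0.92), cholesterol synthesis (0.0619) and antioxidant genes (0.187), and matching members by symbol and product name ended those of cholesterol synthesis (0.133), glucocorticoid-responsive (0.297, 5 members left), fatty acid oxidation (0.169), antioxidant (0.374) and insulin signalling genes (0.289).

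**Figure D3:**
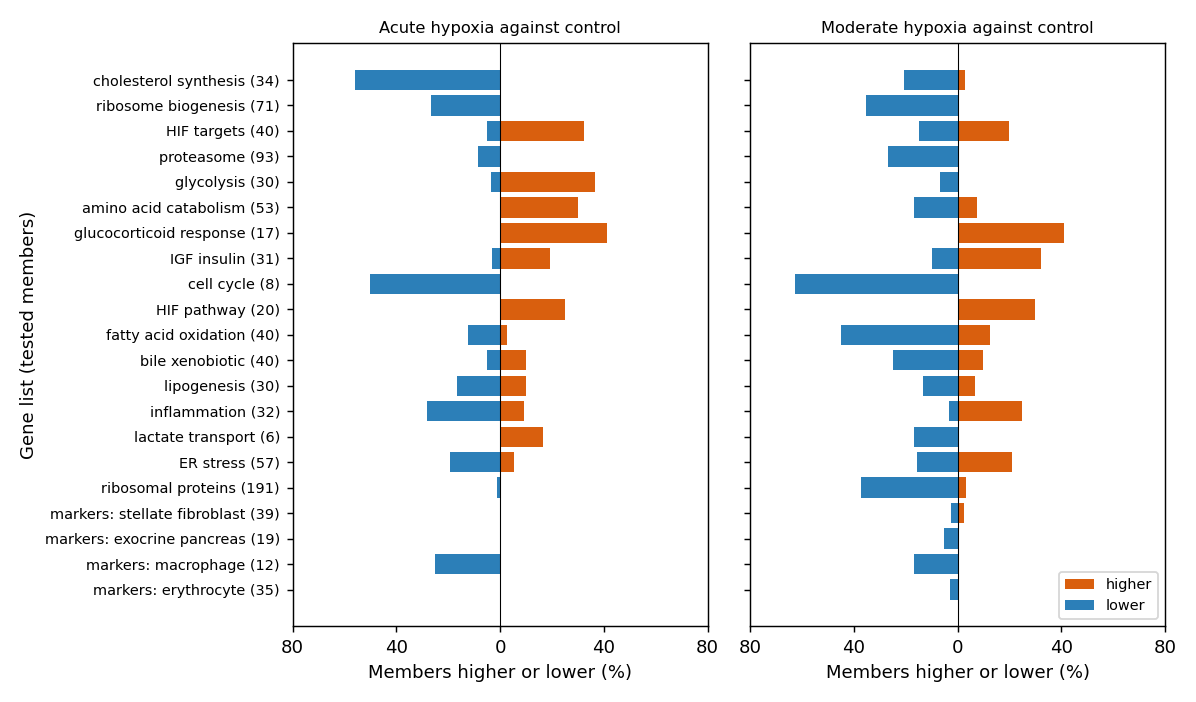
Percent of the tested members of each gene list that were higher (right of 0) or lower (left of 0) than control under median-of-ratios scaling, for the 21 lists called in acute hypoxia, with acute hypoxia on the left and moderate hypoxia on the right. Under this scaling 19 of 34 cholesterol synthesis genes were lower in acute hypoxia and 7 in moderate hypoxia, while 56 of 156 respiration genes, a list not called in acute hypoxia and so not drawn, were lower in moderate hypoxia.

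Acute hypoxia was set against moderate hypoxia to test the difference between the treatments directly. Here the median of all tested genes was -0.21 on the log2 scale, and log2 changes are again given relative to it. Acute phase, glycolysis and amino acid breakdown genes were higher in acute than in moderate hypoxia, relative to other genes, and cholesterol synthesis genes lower. Of 70 acute phase genes 21 were higher and 3 lower, of 30 glycolysis genes 9 and 4, of 53 amino acid breakdown genes 11 and 7, and of 34 cholesterol synthesis genes none and 25. Camera gave adjusted p = 1.74e-13, 7.86e-07, 1.35e-06 and 2.20e-05 in that order, and adjusted p = 0.0664, 0.0664, 0.0664 and 0.75 with an estimated correlation.

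Adjusted over the list alone, those counts were 23 and 3, 10 and 5, 11 and 7, and none and 27, and under median-of-ratios scaling 37 and 2, 18 and 2, 25 and 2, and 1 and 13. After cyclic loess they were 18 and 3, 11 and 4, 15 and 4, and 0 and 18. In acute and moderate hypoxia tpi1b (ncbi_110489325) averaged 63.5 ± 3.70 and 31.4 ± 1.67 FPKM, Mat1a (ncbi_110530927) 136 ± 17.8 and 78.5 ± 12.7, c3 (ncbi_110517348) 1006 ± 183 and 535 ± 57.5, and idi1 (ncbi_100301790) 4.42 ± 2.01 and 17.3 ± 2.87 (SD, n = 3). HIF targets were higher in acute hypoxia, 14 of 40 against 8 lower, also adjusted over the list alone (16 and 3 under median-of-ratios scaling). Camera gave adjusted p = 5.07e-05, and adjusted p = 0.0664 with an estimated correlation. The gene epo (ncbi_110531655) averaged 3.12 ± 0.492 against 1.31 ± 0.140 FPKM. Lactate transport genes were higher, 2 of 6, also adjusted over the list alone (5 under median-of-ratios scaling). By camera they had adjusted p = 0.000593, and adjusted p = 0.102 with an estimated correlation. Inflammation genes were lower, 19 of 32 against 1 higher, also adjusted over the list alone (16 and 2 under median-of-ratios scaling). The camera adjusted p was 0.00394, and adjusted p = 0.75 with an estimated correlation. Endoplasmic reticulum stress genes were lower, 31 of 57 against 3 higher (33 and 3 adjusted over the list alone; 11 and 5 under median-of-ratios scaling). Their adjusted p by camera was 0.00663, and adjusted p = 0.75 with an estimated correlation. The call was lost without moderate hypoxia replicate 2 (adjusted p = 0.0559).

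Respiration genes were called higher, 12 of 156 against 12 lower (2 and 1 adjusted over the list alone; 39 and 1 under median-of-ratios scaling; 19 and 1 after cyclic loess). Camera gave adjusted p = 5.07e-05, and adjusted p = 0.75 with an estimated correlation. Their fitted median was -0.02, which is 0.18 relative to all genes, and their fitted mean -0.02. Hepatocyte markers were called higher, 9 of 34 against 5 lower, also adjusted over the list alone (15 and 4 under median-of-ratios scaling; 6 and 5 after cyclic loess). The camera adjusted p was 0.000129, and adjusted p = 0.309 with an estimated correlation. Their fitted median was 0.07, which is 0.27 relative to all genes, and their fitted mean -0.05. Bile acid and xenobiotic genes were called higher, 8 of 40 against 9 lower (9 and 10 adjusted over the list alone; 13 and 1 under median-of-ratios scaling; 8 and 2 after cyclic loess). Their adjusted p by camera was 0.00191, and adjusted p = 0.105 with an estimated correlation. Their fitted median was -0.04, which is 0.17 relative to all genes. Exocrine pancreas markers were called higher, 3 of 19 against 1 lower (none and 1 adjusted over the list alone; 4 and 1 under median-of-ratios scaling; 2 and 1 after cyclic loess). By camera they had adjusted p = 4.91e-05, and adjusted p = 0.75 with an estimated correlation. Ribosomal protein genes were called higher although 15 of 191 were higher and 27 lower (12 and 24 adjusted over the list alone; 58 and 7 under median-of-ratios scaling; 16 and 30 after cyclic loess). The direction turned to lower after cyclic loess (adjusted p = 0.196), quantile normalization (0.33) and by fry (0.509). The camera adjusted p was 0.0101, and adjusted p = 0.863 with an estimated correlation. Their fitted median was -0.07, which is 0.13 relative to all genes, and their fitted mean -0.07; the call was lost without acute hypoxia replicate 1 (adjusted p = 0.0519).

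The keratin genes e1 (ncbi_100137013) and k13 (ncbi_100136068) were higher in acute hypoxia, at 3.01 ± 0.55 (SE, adjusted p = 0.00383) and 2.92, as were the polyubiquitin genes UBB (ncbi_118936268) and UBB (ncbi_110517804), at 3.18 and 2.52. In that order they averaged 0.0293, 0.168, 0.189 and 0.0747 FPKM in moderate hypoxia, near 0, and 3.28, 4.18, 5.09 and 2.57 in acute hypoxia. Control libraries spread widely, at 1.97 ± 1.86, 2.03 ± 1.69, 4.90 ± 4.56 and 2.32 ± 2.14 FPKM (SD, n = 3). The polyubiquitin family shares near-identical sequence, so reads may be split between its genes. The largest falls were those of Relb (ncbi_110507414) at -3.17 ± 0.32 (adjusted p = 0.000123), pla2g3 (ncbi_110536804) at -3.13, MSTRG.10100 at -3.08, the apolipoprotein A-IV gene (ncbi_110523359) at -2.81, USP9X (ncbi_110504735) at -2.81 and RIPK2 (ncbi_110526239) at -2.69. All 6 kept their calls with each library left out and under 3 other scalings, as did 4 of the 6 genes named for the largest rises.

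In total 4477 genes passed limma's test between acute and moderate hypoxia, 593 higher and 3884 lower (13.2% higher); median-of-ratios scaling gave 1629 higher and 1642 lower of 3271 (49.8% higher), and 592 and 1642 genes were called under both. Under the deposited scaling groups did not overlap for 45.6% of genes, against 10% by chance, a share to which the shift of all genes may add. The count was 2943 after quantile normalization and 2814 after cyclic loess, and cyclic loess ended the calls of hepatocyte marker (adjusted p = 0.92), bile acid and xenobiotic (0.192), exocrine pancreas (0.0519) and ribosomal protein genes (0.196). Matching members by symbol and product name ended that of HIF targets (0.238).

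Both hypoxia groups were then compared with each other through their calls against control. In both groups hmox (ncbi_110485518), epo (ncbi_110531655), Egln3 (ncbi_110505778), Tat (ncbi_110494358), zbtb16a (ncbi_110537608) and foxo1a (ncbi_110534227) were higher, and mcm3 (ncbi_110529168), nhp2 (ncbi_110533406) and the apolipoprotein A-IV gene (ncbi_110523359) were lower. In all, 288 genes were higher and 142 lower in both, against 103.1 and 32.6 for independent lists of the same lengths, and 41 moved in opposite directions, against 179, of which 40 were higher in moderate and lower in acute hypoxia. Under median-of-ratios scaling 494 genes moved in the same direction in both, 260 of them higher and the rest lower, and 22 moved in opposite directions, 12 of them higher in moderate hypoxia. In 50 simulations all 9 libraries were redrawn with no gene changed, and both comparisons used the same 3 simulated controls. The calls of the 2 comparisons then shared 0.04 genes on average and 1 at most. With no gene changed almost none is called, so that count cannot show what changed groups share through common controls. The covariance of the log2 fold changes was 0.0523 against a simulated 0.0128, a difference of 0.0394, and their correlation across genes was 0.399 against a simulated 0.502. The controls are too few to be split into 2 sets of 2 or more, so part of the excess may come from the shared controls. The count of 430 genes fell to 178 without control replicate 1, 251 without acute hypoxia replicate 2 and 265 without control replicate 2.

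**Figure D4:**
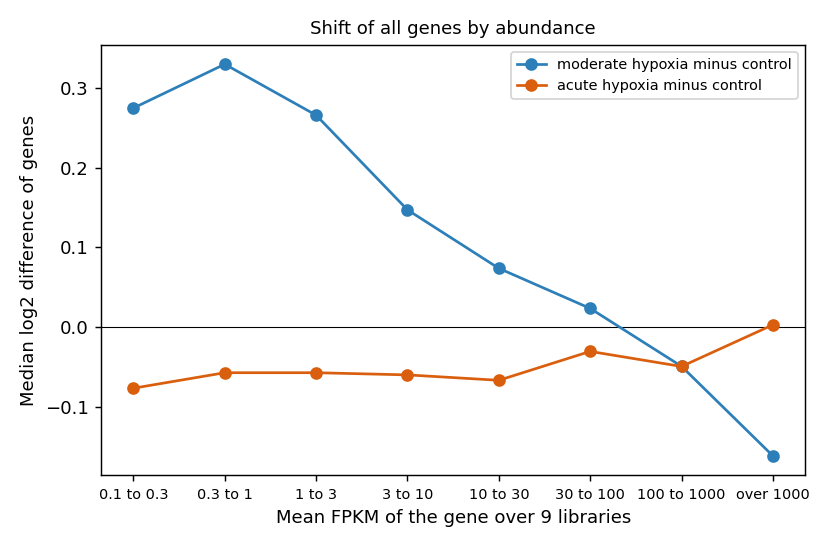
Median log2 difference from control of all genes, in bins of mean FPKM over the 9 libraries, for moderate hypoxia and acute hypoxia, computed with a pseudocount of 0.01. In moderate hypoxia the median runs from 0.33 at 0.3 to 1 FPKM to -0.16 above 1000 FPKM, while in acute hypoxia it stays between -0.08 and 0.00.

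The title of the series names glut1a, a glucose transporter gene, and the long noncoding RNA LOC110519952, so the glut1 genes are reported although they lie below the filter of 1 FPKM. The gene glut1a (ncbi_100135909) averaged 0.528 ± 0.243 FPKM in control, 0.698 ± 0.119 in moderate hypoxia and 1.20 ± 0.118 in acute hypoxia (SD, n = 3), and each acute library lay above each control library. In limma without the filter the log2 fold change in acute hypoxia against control was 0.75 ± 0.18 (SE, adjusted p = 0.0818), which did not pass the threshold, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Against moderate hypoxia the change was 0.51 (adjusted p = 0.0988; 0.70 and 0.048 under median-of-ratios scaling), and that of moderate hypoxia against control was 0.24 (adjusted p = 0.438). Without single libraries the acute change ran from 0.56 to 0.91. With pseudocounts of 0.1 and 1 in place of 0.5 it was 1.12 and 0.54 (limma adjusted p = 0.0877 and 0.0759), so its size depends on the pseudocount. A further copy, Slc2a1 (ncbi_110494474), averaged 0.217 ± 0.118, 0.322 ± 0.0181 and 0.572 ± 0.104 FPKM in control, moderate and acute hypoxia, with a change of 0.59 ± 0.14 in acute hypoxia (SE, adjusted p = 0.0718). With pseudocounts of 0.1 and 1 that change was 1.15 and 0.37. The authors' deposited log2 fold changes of the 2 genes, acute hypoxia against control, were 1.18 and 1.40, with an FDR of 0.00451 and 0.0253. These are log2 ratios of group means without the added 0.5, from the table with other gene models. They are therefore not the same measure as the fitted changes. The copy glut1b (ncbi_100135910) and 4 further genes annotated as glucose transporter member 1 were listed at 0 in all 9 libraries. LOC110519952 and microRNAs were not analysed here.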

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

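The tests of the abundance trend, of lists after cyclic loess, of the pancreas markers and of other splits of the libraries were chosen only after the results were seen. Of the 41 genes that passed limma's test in opposite directions in the 2 hypoxia groups, each also with a tested difference between acute and moderate hypoxia, 12 that did so under median-of-ratios scaling too are listed here because the 2 groups differ in direction. Of these, 11 were higher in moderate and lower in acute hypoxia. That one-sided split goes with the deposited scaling: among all genes called in opposite directions 40 were higher in moderate and lower in acute hypoxia and 1 the other way, against 12 and 10 under median-of-ratios scaling and 21 and 8 after cyclic loess. The difference of acute from moderate hypoxia, relative to the median of all tested genes, was -1.82 for a putative per-hexamer repeat protein gene (ncbi_118939268), -1.54 for tlcd4a (ncbi_110535492), -1.51 for the kinase gene mknk1 (ncbi_110537830), -1.47 for Bach1 (ncbi_110533253), a repressor of heme oxygenase genes, -1.46 for Nfkb2 (ncbi_110527634), an NF-kappa-B subunit gene, and -1.40 for irak3 (ncbi_101268966), a regulator of innate immune signalling. It was -1.35 for Suco (ncbi_110524508), -1.10 for the splicing kinase gene Clk2 (ncbi_110496023), -0.83 for a gene of the splicing particle U2 (ncbi_110500625), -0.82 for MTTP (ncbi_110497503), which loads lipid onto lipoproteins, and -0.81 for the ubiquitin ligase gene ubr2 (ncbi_110527212). CYP7A1 (ncbi_110508825), the first enzyme of bile acid synthesis, went the other way, at 1.61. In genes selected for opposite calls against the same controls, the difference between the hypoxia groups is nearly fixed in advance. That it was called with each of the 9 libraries left out for all 12 genes therefore adds no support. Among them all 3 calls together held in each of these fits only for tlcd4a.

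Genes of low and middle abundance sat higher in the moderate hypoxia libraries, with a median shift from control of 0.33 on the log2 scale at 0.3 to 1 FPKM and -0.16 above 1000 FPKM. A single scale factor per library, as when a few abundant genes take another share of the total, is excluded as the whole cause: over the 9 pairs of a moderate and a control library the shift at 1 to 3 FPKM exceeded that at 100 to 1000 FPKM by at least 0.20, and between control libraries by at most 0.0943. A flat floor of reads such as genomic DNA is also excluded as the whole cause. The shift grew by at most 0.10 from 1 to 3 FPKM to 0.3 to 1 FPKM. A flat addition that made the whole shift at 1 to 3 FPKM would give at least 0.28. A smaller floor together with a scale factor was not tested. Moderate hypoxia itself and RNA quality or handling that differed between the same libraries cannot be told apart, because the shift of at least 0.15 at 1 to 3 FPKM is present in all 9 pairs and the design confounds them.

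The abundance trend could also lower lists of abundant genes in moderate hypoxia. The calls of acute phase genes (adjusted p = 0.198), hepatocyte markers (0.448) and ribosomal protein genes (0.92) ended after cyclic loess, which removes the trend, because their medians relative to all genes moved towards 0, so the trend may account for these calls. Acute phase genes and hepatocyte markers had median FPKM of 541 and 388, where 433 genes lay at 100 to 1000 FPKM and 76 above. Their members are part of the genes that set the trend there. A lost call therefore cannot tell the trend from a fall of these genes themselves. Relative to all genes, the medians of acute phase, hepatocyte marker and ribosomal protein genes went from -0.32 (quartiles -0.45 and -0.13) to -0.10 (quartiles -0.23 and 0.11), from -0.29 (quartiles -0.44 and -0.05) to -0.05 (quartiles -0.23 and 0.18) and from -0.17 (quartiles -0.37 and 0.01) to 0.03 (quartiles -0.19 and 0.21). For respiration genes it stays open: the list was still called (adjusted p = 0.000321; under the deposited scaling adjusted p = 0.612 with an estimated correlation), but its median went from -0.24 (quartiles -0.42 and -0.04) to -0.14, with quartiles of -0.36 and 0.05 that span 0. Ribosome biogenesis and proteasome genes, with median FPKM of 3.02 and 5.97, lie where the trend lowers genes little or not at all relative to others (a shift of 0.27 at 1 to 3 and 0.15 at 3 to 10 FPKM, against 0.15 over all tested genes), so cyclic loess does not test it for them.

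Exocrine pancreas markers were called higher in acute hypoxia (camera adjusted p = 0.038), a call that ends with an estimated correlation (adjusted p = 0.743) and under median-of-ratios, quantile and cyclic loess scaling (0.102, 0.106 and 0.135). Trout pancreas is spread through tissue near the liver, and pancreas carried into single samples may account for the call: within groups the members moved together, with an estimated correlation of 0.569, and their median per library was -1.28, 0.15 and 0.61 in control, -0.94, 1.11 and -0.88 in moderate hypoxia and 1.11, 0.72 and -0.23 in acute hypoxia. An effect of acute hypoxia stays open, since an exact permutation test of these medians, acute against control, gave p = 0.4 and the groups overlap.

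The 6 libraries of each comparison split into 3 and 3 in 10 ways, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes: 4041 in moderate hypoxia against control with 1 in the highest other split, 1075 in acute hypoxia against control with 0 in the highest other, and 4477 in acute against moderate hypoxia with 0 in the highest other.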

How the results depend on the processing

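Cyclic loess, quantile normalization of the lists, matching of list members by symbol and product name, the other quantification and 2 scalings of the glut1 genes were tests chosen only after seeing the data. Of the alternatives over 8 main results 100 stayed within the bounds set for no change and 23 moved. A count was said to move when it differed from the main one by a ratio of more than 1.5. For glut1a the bound was the sign and the side of the threshold. Directions and the genes or lists behind a count were not compared, so the 100 include counts by fry and by median-of-ratios scaling that rest partly on other calls. A minimum of 5 FPKM, which tests fewer genes, gave 1257 genes in moderate hypoxia against control, 571 in acute hypoxia against control and 1443 in acute against moderate hypoxia, and an added log2 fold change of at least 1 gave 380, 181 and 453. Without a filter 700 genes were called in acute hypoxia and 273 in the same direction in both groups; the cause was not tested. Between acute and moderate hypoxia quantile normalization gave 2943 genes and cyclic loess 2814; the cause was not tested.

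With 1 library left out, which leaves fewer samples, the counts ran from 2623 (without control replicate 1) to 3510 in moderate hypoxia, from 462 (without control replicate 1) to 883 in acute hypoxia, with 588 without acute hypoxia replicate 2 and 662 without control replicate 2, and from 3004 to 3928 between the hypoxia groups. Genes changed in the same direction in both groups ran from 178 (without control replicate 1) to 368, with 251 without acute hypoxia replicate 2 and 265 without control replicate 2. The lists called ran from 9 to 14, from 17 to 22 and from 12 to 14, and the change of glut1a in acute hypoxia from 0.56 to 0.91. With all libraries, pseudocounts of 0.1 and 1 moved that change of glut1a further, to 1.12 and 0.54. The other quantification called 976 genes in acute hypoxia, 861 of them shared in direction.

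The lists called numbered 12 in moderate hypoxia, 21 in acute hypoxia and 13 between them. Camera with an estimated correlation called 0, 1 and 0, with 3, 8 and 6 lists at an unadjusted p under 0.05. By fry, which asks whether members moved together in 1 direction without regard to other genes, 17, 14 and 19 were called. The directions differ: fry called 15 higher and 2 lower in moderate hypoxia, 7 and 7 in acute hypoxia, and 4 and 15 between them, against 2 and 10, 10 and 11, and 10 and 3 by camera, so its counts do not stand for the same calls. In moderate hypoxia quantile normalization, cyclic loess and matching by symbol and product name called 7 each, the last over the 31 lists that kept at least 5 members, which leaves the calls of cell cycle genes and, in acute hypoxia, of macrophage markers without a value. Of 641 alternatives over the 46 calls 512 held, 121 were weaker and 8 turned direction, none of them past the threshold: antioxidant genes in moderate hypoxia under fry (adjusted p = 0.956), ribosomal proteins there under quantile normalization (0.944) and cyclic loess (0.92), ribosomal proteins in acute hypoxia without control replicate 2 (0.866, the range with each library left out being 1.61e-06 to 0.866), and, between the hypoxia groups, respiration genes under fry (0.812) and ribosomal proteins under fry (0.509), quantile normalization (0.33) and cyclic loess (0.196). Of 5344 alternatives over 367 changes of named genes 4837 held, 429 were weaker, 78 stronger and 0 reversed.

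A replicate block in limma, as if the numbers paired the libraries, gave 3557, 794 and 3984 genes, 317 in both groups, and 12, 21 and 13 lists. In acute hypoxia the block ended the call of stellate cell markers (adjusted p = 0.0543) and called respiration genes lower (0.0412, against 0.0542 without it), so that 9 lists were higher and 12 lower instead of 10 and 11. No shared effect of the numbers was detected: deviations from group means of same-numbered libraries correlated at -0.131 to 0.0806 over 9 pairs, and those of other libraries at -0.106 to 0.13, and 0 libraries correlated best with their own number in both other groups. With so few libraries this cannot exclude that a number marks a shared tank or day, on which the labels are silent. Not run were the comparison of long noncoding genes, since matched genes are protein-coding but for 1, and the relation of LOC110519952 to glut1a. Depth could not be counted, so no limit on low values is given.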

Other observations

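The test of glucocorticoid-responsive genes below was chosen only after the results were seen. Of the lists not called in moderate hypoxia against control, clock genes had 12 higher and 2 lower (10 and 5 under median-of-ratios scaling; camera adjusted p = 0.263) and tricarboxylic acid cycle genes 12 higher and none lower (5 and 3; camera adjusted p = 0.297). The detoxification genes cyp1a1 (ncbi_110526570) and cyp1a3 (ncbi_100142632), near-identical copies that may share reads, averaged 109 ± 11.2 and 62.0 ± 10.5 FPKM in moderate hypoxia (SD, n = 3), 341 ± 20.8 and 202 ± 9.70 in control and 388 ± 33.3 and 272 ± 28.6 in acute hypoxia, with relative changes of -1.80 and -1.87 in moderate hypoxia.

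Of the 17 listed glucocorticoid-responsive genes 6 (35.3%) were higher in both hypoxia groups, zbtb16a (ncbi_110537608), FKBP5 (ncbi_110494097), fkbp5 (ncbi_110528325), klf9 (ncbi_110525414) and 2 Tsc22d3 genes (ncbi_110504506 and ncbi_110489223), against 288 of all 13803 tested genes (2.09%). The list was already called higher in each group, with 11 and 7 of 17 higher in moderate and acute hypoxia. Those calls end with an estimated correlation (adjusted p = 0.438 and 0.0785) and, in moderate hypoxia, with members matched by symbol and product name (0.297). Fisher's exact test of the excess, two-sided (p = 7.99e-07), restates these calls, so it decides nothing about a hormone response shared by both groups, which stays open.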
